A study of Mus musculus with 9 samples.

How the data were processed

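Single-cell RNA was measured in 9 libraries from subcutaneous tumours grown from the mouse lung carcinoma line LLC in female C57BL/6 mice. The groups were PBS (the negative control), UV-TMPs (the positive control) and MW-TMPs, with 3 libraries each. The treatment protocol of every sample, PBS included, reads MW-TMPs, so the groups were taken from the title and the treatment characteristic, and this doubt bears on every group value. Per the labels, the matrices came from magnetic beads with barcodes in a honeycomb plate and from the BD Rhapsody pipeline, with alignment to GRCm39. The same labels also name 10X Genomics and Cell Ranger 2.1.1, which belong to another platform, and this contradiction could not be settled. The integer cell labels are of the BD Rhapsody kind. The deposited values are raw UMI counts per gene and cell, with 1 matrix per library. The annotation release, the cell-calling settings and the treatment of reads that match several genes are not stated. The labels do not say whether the libraries of a group came from separate mice, so every p-value below measures the spread between these libraries, which may be technical in part.

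The 9 matrices were joined by gene symbol, with a count of 0 where a library did not list a gene. Of 31224 genes listed in at least one library, 23596 were listed in all. Cells with at least 500 UMIs, at least 200 genes and under 25% mitochondrial UMIs were kept. This removed 226 of 91078 barcodes. The lowest UMI count of a barcode lay between 2435 and 7272 in the 9 libraries, so a stricter limit had been applied before deposition. Scrublet, as in scanpy 1.11.5, was run on each library with an expected doublet rate of 0.06. Its automatic threshold marked only 4 cells, so it did not work as a doublet filter here. The 4 cells were left out, which left 90848 cells.

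Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were scaled and reduced to 38 principal components, the number given in the labels. A graph of 20 nearest neighbours was clustered with Leiden (leidenalg 0.10.2) at resolution 1, which gave 27 clusters. No batch integration was applied. Clusters were named from marker genes of 18 cell types fixed before the data were examined. A name needed at least 3 markers, each with a UMI in at least 10% of the cells. Limits set after seeing the data were added: at least 100 CPM of Xist, which cells of the female host express, for a host class, and under 10 CPM for the malignant-like class. Clusters that failed a limit stayed unnamed. So did clusters whose 10 top genes by fold held more markers of another type than of their nearest one. Class names carry "-like", since they rest on markers alone, and markers used for a name are not independent evidence about the class.

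UMIs were summed per library over all cells (whole tumour) and within each class. By a plan fixed beforehand, the classes to test were malignant-like, macrophage/monocyte-like, neutrophil-like, dendritic cell-like, T cell-like and NK cell-like cells. Fibroblast-like, endothelial-like and pericyte/smooth muscle-like cells were counted but their genes were not tested. A library entered with at least 30 cells of a class, and a comparison was fitted with at least 2 libraries in each group. Sums were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test), with the 3 groups in one fit. The threshold was a Benjamini-Hochberg adjusted p of 0.05, with no limit on the fold. Folds are given as log2 changes with their standard error (SE), and levels as CPM as edgeR computes them with the standard deviation (SD) over the libraries. Neutrophil-like and NK cell-like cells were too few to test. Dendritic cell-like cells could be tested only for UV-TMPs against PBS, and T cell-like cells only for MW-TMPs against UV-TMPs. Where a group held no counts of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% interval. Intervals and floors cover counting error only.

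Before the data were examined, 28 gene lists were fixed. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with adjustment over the lists of a class and comparison. Camera with an estimated correlation and fry (a rotation test of each list on its own) were run beside it. For each list, its members past the threshold were counted over all genes tested and adjusted over the list alone. Cell numbers per class were tested with edgeR with the kept cells of a library as offset, and with exact two-sided permutation tests. A test of 3 against 3 cannot give a p below 0.1. The exact test over the 3 groups has 1680 assignments.

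The genes named were set by a rule fixed beforehand: in the whole tumour up to 8 genes in each direction with the smallest p. In a class up to 6 in each direction with the largest fold and a mean of at least 20 CPM were taken. Up to 4 members of each called list with the smallest p were added, and Hmgb1, Calr, Tlr4 and Ager always. With fewer than 3 called genes, the 3 of smallest p are given as values. Predicted genes and pseudogenes were counted but not named. For every named gene, the share of its last 1000 bases made of 31-base words found in another gene was computed from GENCODE transcripts (GRCm39). A high share makes a level uncertain.

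The tests were checked on simulated counts with the dispersion of these data and 200 changed genes. For UV-TMPs against PBS, a fold of 2 was recovered for 65.7% of changed genes in malignant-like cells, 53.7% in macrophage/monocyte-like cells and 14.9% in dendritic cell-like cells. For MW-TMPs against PBS it was recovered for 70.1% in malignant-like cells.

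Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, a filter of 10 counts in 3 libraries, and only the 2 groups compared. Others were the replicate number as a block, each library left out in turn, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), Leiden resolution 2, immune cells as the denominator and genes listed in all libraries. Chosen after seeing the data were leaving out the 6% of cells with the highest doublet scores, a common ratio of 0.401 of lowest to median UMI count, and leaving out host cells with more than 3 UMIs of Hmga2, Igf2bp2 and Krt8. Adding a cluster with Lum and Dpt among its leading genes to the malignant-like class, a fit of macrophage/monocyte-like against malignant-like cells, and a correction for transcript length were also chosen then. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.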

Results

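The series title asks about microparticles made from tumour cells with microwaves (MW-TMPs), immunogenic cell death and HMGB1, a nuclear protein that acts as a danger signal outside the cell. LLC cells (500000 per mouse) were placed under the skin of female C57BL/6 mice, and groups of 6 mice were treated 5 times, every 2 days. Tumours of 3 groups were sequenced as single cells: PBS, MW-TMPs, and UV-TMPs as the positive control, with 3 libraries per group. The PBS libraries held 152833989, 164017966 and 144992427 UMIs, with 10885, 9348 and 7231 kept cells. The UV-TMPs libraries held 113040987, 112741488 and 115402867 UMIs, with 7627, 9017 and 13237 cells, and so were shallower in total than those of the other 2 groups. The MW-TMPs libraries held 141439853, 155105406 and 156904737 UMIs, with 8063, 12703 and 12737 cells. The median UMI count per cell lay between 7856 and 18154. Below, a level is a mean in CPM ± SD and a log2 change is given ± SE, over 3 libraries per group unless stated otherwise. Adjusted p-values of genes and cell shares are from edgeR, and those of gene lists from camera.

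Most cells were malignant-like (73816 cells), marked by LLC genes and almost no Xist. The others with a name were 6321 macrophage/monocyte-like, 1012 fibroblast-like, 649 endothelial-like, 411 T cell-like, 344 dendritic cell-like, 217 pericyte/smooth muscle-like, 213 NK cell-like and 57 neutrophil-like cells. Another 7808 cells stayed unnamed. T cell-like cells made up 0.256% ± 0.152 (SD, n = 3) of cells in PBS, 0.705% ± 0.204 in UV-TMPs and 0.355% ± 0.0898 in MW-TMPs. Dendritic cell-like cells made up 0.236% ± 0.156, 0.683% ± 0.226 and 0.243% ± 0.121, and NK cell-like cells 0.125% ± 0.108, 0.407% ± 0.206 and 0.190% ± 0.106. Macrophage/monocyte-like cells made up 8.50% ± 2.42 in PBS, 7.83% ± 1.29 in UV-TMPs and 4.79% ± 1.69 in MW-TMPs, and malignant-like cells 76.2% ± 5.84, 81.8% ± 3.11 and 85.7% ± 0.638. The malignant-like share leaves out an unnamed cluster with 859 CPM of the LLC gene Hmga2 and 2.0 CPM of Xist. Its top genes held more fibroblast than LLC markers, which left it unnamed. That cluster held 10.4% ± 3.69 of cells in PBS, 4.52% ± 3.29 in UV-TMPs and 5.06% ± 1.87 in MW-TMPs, so the naming rule bears on the malignant-like share. Of the 49 neutrophil-like cells in PBS, 45 came from PBS replicate 3. The neutrophil-like count rests on the Xist limit. An unnamed cluster of 577 cells, nearest to neutrophils by its markers, fell below that limit (7.1 CPM), with 25.6% of its cells from PBS replicate 3. PBS replicate 3 held 0 NK cell-like cells of 7231, which allows a share of up to 0.0415%. UV-TMPs replicate 1 held 0 neutrophil-like cells of 7627, which allows up to 0.0393%.

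No class share passed the threshold in any of the 3 comparisons. The T cell-like share of UV-TMPs against PBS had a log2 change of 1.44 ± 0.45 (edgeR adjusted p = 0.123), and the dendritic cell-like share one of 1.51 ± 0.65 (adjusted p = 0.153). The macrophage/monocyte-like share of MW-TMPs against PBS had a log2 change of −0.83 ± 0.34 (adjusted p = 0.191). With the replicate number as a block it passed the threshold (−0.8584), as did the endothelial-like share (−0.9865). By the rule given below the number was not taken to pair the libraries, but that rule cannot exclude a pairing of some of them. In the exact permutation test over the 3 groups, the adjusted p was 0.129 for dendritic cell-like, malignant-like and T cell-like shares, and the pairwise exact tests reached 0.1, the smallest p they can give, for T, dendritic and NK cell-like cells in UV-TMPs against PBS. They did so too for macrophage/monocyte-like and malignant-like cells in MW-TMPs against PBS, and for these and T and dendritic cell-like cells in MW-TMPs against UV-TMPs. Without PBS replicate 1, the T cell-like share of UV-TMPs against PBS passed the threshold (log2 change 2.0573). It also passed when host cells with more than 3 UMIs of LLC markers were left out (2.4274). With immune cells alone as the denominator, the T cell-like share passed the threshold for UV-TMPs (log2 change 1.4524) and for MW-TMPs (1.3032) against PBS. Macrophage/monocyte-like cells are part of that denominator, and their share of kept cells was 8.50% in PBS, 7.83% in UV-TMPs and 4.79% in MW-TMPs. For MW-TMPs, a gain of T cell-like cells is thus not parted from a fall of macrophages. Among T cell-like cells, 42.3% held more than 3 UMIs of LLC markers, against 3.8% of macrophage/monocyte-like cells, so many of them carried RNA of malignant cells.

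**Figure D1:**
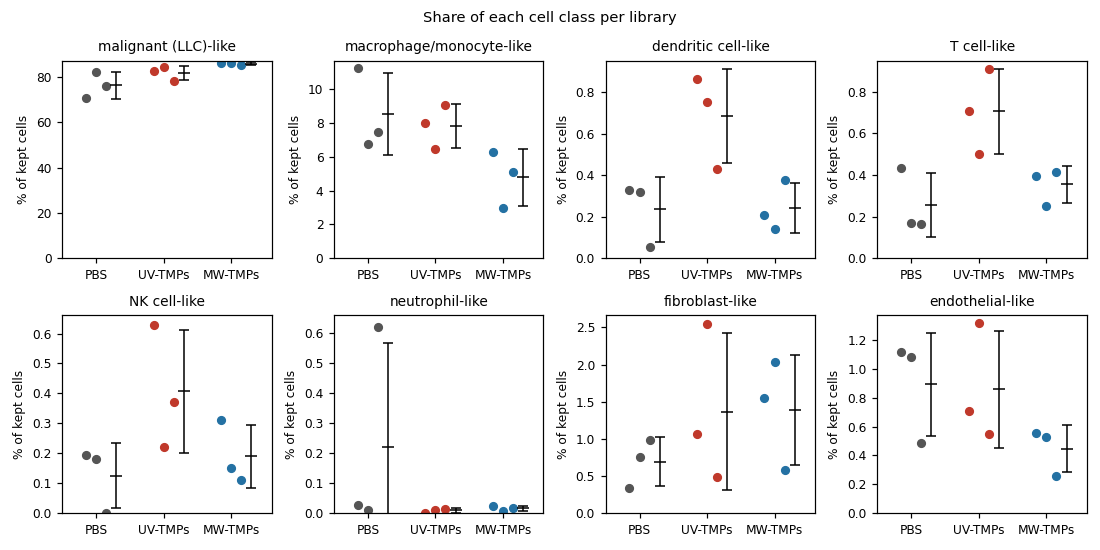
Share of kept cells (percent, y axis) of 8 cell classes in the PBS, UV-TMPs and MW-TMPs groups. Each point is a library and each line with its bar the mean and SD of 3 libraries. The T cell-like mean was 0.256% in PBS and 0.705% in UV-TMPs, and the macrophage/monocyte-like mean 8.50% in PBS and 4.79% in MW-TMPs.

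UV-TMPs against PBS asks what the positive control did to the tumour. In the whole tumour, the lists of the interferon gamma response, of class I and class II antigen presentation and of cytotoxic effectors lay higher after UV-TMPs at camera's preset correlation. Each had an adjusted p of 0.612 with an estimated correlation. Gbp2, an interferon-induced GTPase (chromosome 3, 142326349 to 142343779, GRCm39), rose from 30 ± 8.36 to 140 ± 79.8 CPM (log2 change 2.22 ± 0.40). The class II chain H2-Aa (chromosome 17, 34493404 to 34506798) rose from 35.8 ± 18.3 to 149 ± 68.9 CPM. Lyve1, a hyaluronan receptor of resident macrophages and lymphatic vessels (chromosome 7, 110448585 to 110462460), fell from 53.5 ± 17.1 to 10.6 ± 1.23 CPM (log2 change −2.34 ± 0.23), and the scavenger receptor Cd163 fell from 17.5 ± 5.17 to 2.93 ± 1.02 CPM.

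By list, 19 of the 23 interferon gamma response genes rose and 0 fell over all genes tested (21 and 1 adjusted over the list alone, adjusted p = 2.11e-09). Among them Icam1 changed by 0.77 ± 0.14, Gbp5 by 0.98, and the list's adjusted p was 0.612 with an estimated correlation. Of 21 cytotoxic effector genes, 11 rose and 0 fell (14 and 0 adjusted over the list alone, adjusted p = 2.28e-08, and 0.612 with an estimated correlation). The T cell-like share, 0.256% in PBS and 0.705% in UV-TMPs, and the NK cell-like share, 0.125% and 0.407%, moved with this list and with that of regulatory T cells below. The chemokine Xcl1 rose from 0.0810 ± 0.0543 to 0.817 ± 0.193 CPM, Ifng from 0.138 ± 0.0294 to 0.739 ± 0.284 CPM, and the granule protein Nkg7 by 2.14 ± 0.52. Of 18 class I presentation genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with H2-K1 at a log2 change of 0.90 and the immunoproteasome subunit Psmb10 at 0.75. Of 13 class II genes 5 rose and 1 fell (8 and 2 adjusted over the list alone), with Cd74 up by 1.78 and the protease Lgmn down by 0.75. The dendritic cell-like share, 0.236% in PBS and 0.683% in UV-TMPs, moved with the class II list. Both presentation lists had an adjusted p of 0.612 with an estimated correlation.

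Of 25 type I interferon response genes, 8 rose and 1 fell, also adjusted over the list alone: Rsad2 rose by 1.08 ± 0.26 and Oas1a fell by 1.31 ± 0.22 (adjusted p = 0.0222, and 0.753 with an estimated correlation). Of 12 regulatory T cell genes 5 rose and 0 fell, also adjusted over the list alone, among them Foxp3 (0.0936 ± 0.0315 to 0.287 ± 0.134 CPM) and Il2ra (0.449 ± 0.203 to 1.54 ± 0.481 CPM). Ctla4 rose from 44.2 ± 8.69 to 175 ± 83.6 CPM, and its level within malignant-like cells was 179 ± 86.6 CPM after UV-TMPs. Of 20 genes of alternatively activated macrophages, 6 fell and 1, the growth factor Vegfa, rose (8 and 1 adjusted over the list alone). The mannose receptor Mrc1 fell by 1.29 ± 0.28. Both lists had an adjusted p of 0.612 with an estimated correlation. At the preset correlation, the type I call ended without PBS replicate 2 (adjusted p = 0.166) or UV-TMPs replicate 1 (0.326), that of the class II list without UV-TMPs replicate 1 (0.0515) and that of the regulatory T cell list without UV-TMPs replicate 3 (0.0552). The call of Foxp3 ended without PBS replicate 2 (adjusted p = 0.0650), PBS replicate 3 (0.0891) or UV-TMPs replicate 1 (0.121), and those of Il2ra and Rsad2 without PBS replicate 3 or UV-TMPs replicate 1. Without UV-TMPs replicate 1, those of H2-Aa, H2-K1 and Nkg7 ended as well.

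Among the 8 genes of smallest p that rose, Igkc, the antibody kappa constant region, went from 0.114 ± 0.101 to 12.2 ± 2.07 CPM. The antibody joining chain Jchain was 109-fold higher (95% interval 36.9 to 533, from 242 against 3 counts). Both rest mostly on 3 cells of the T cell-like class, 1 in each UV-TMPs library, which held 3759 of the 4114 Igkc UMIs and 238 of the 242 Jchain UMIs of UV-TMPs (a test chosen after the result was seen). The phospholipid flippase Atp10d rose from 10.7 ± 2.09 to 32.6 ± 3.70 CPM, and Kank4, Rfx4, Atp6v0a4, Cblc and Stra6l rose by 1.47 to 2.15. Among those that fell were Ap5b1 (−2.16), Hoxd9 (−1.32), Ubtd1 (−1.33), Akap8l (−1.13), Retreg2 (−0.94), Zfp644 (−0.81) and Kbtbd2 (−0.75).

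In all, 5016 of 21088 genes passed the threshold in the whole tumour, 2466 higher and 2550 lower after UV-TMPs. The count was 2683 without PBS replicate 1, 2633 without PBS replicate 3, 2417 without UV-TMPs replicate 1 and 2790 without UV-TMPs replicate 2. Across genes, the log2 change went with transcript length (Spearman −0.279), so that genes with short transcripts lay higher after UV-TMPs. Genes are not independent replicates.

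Within macrophage/monocyte-like cells, the class II, interferon gamma and type I interferon lists lay higher after UV-TMPs at the preset correlation (adjusted p = 0.161, 0.161 and 0.176 with an estimated correlation). H2-Aa rose from 407 ± 204 to 2367 ± 1248 CPM (log2 change 2.54 ± 0.40, adjusted p = 0.00624), with H2-Ab1, H2-Eb1 and the invariant chain Cd74 up by 2.21 to 2.46. Ifnb1, which encodes interferon beta (chromosome 4, 88440262 to 88441011), rose from 20.5 ± 7.96 to 135 ± 93.5 CPM. Cd163 (chromosome 6, 124281606 to 124307560) fell from 318 ± 50.3 to 66.2 ± 15.2 CPM, and Ms4a4a and the complement regulator Cd55 fell by 2.29 and 2.41. Cells of this class lay in different clusters at Leiden resolution 2, which was looked at after these results. The cluster led by Cxcl9, with Cd74 and H2-Aa, held 8.34% ± 6.00 of the class in PBS and 39.4% ± 24.2 in UV-TMPs, and the cluster led by Lyve1, with Mrc1 and Cd163, 44.6% ± 3.20 and 15.3% ± 4.84. The sums over the class do not part a shift between these clusters from a change inside them.

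Of 22 interferon gamma response genes 19 rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p = 1.92e-23, and 0.161 with an estimated correlation). Examples were Igtp (1.94 ± 0.26), the feedback inhibitor Socs1 (1.86 ± 0.25), Irf1 (1.38 ± 0.19) and the T cell attractant Cxcl10, which went from 511 ± 74.4 to 1663 ± 716 CPM. Of 25 type I interferon genes 15 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 2.19e-12, and 0.176 with an estimated correlation). Ifit1 rose from 98.7 ± 15 to 364 ± 185 CPM and Rsad2 from 188 ± 3.00 to 599 ± 209 CPM. Of 18 class I genes 11 rose (16 adjusted over the list alone, adjusted p = 1.99e-12, and 0.198 with an estimated correlation), with the peptide transporter Tap1 up by 1.30 ± 0.16. Of 11 class II genes 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 3.65e-10, and 0.161 with an estimated correlation). Of 21 chemokine genes 6 rose and 0 fell (9 and 1 adjusted over the list alone, adjusted p = 0.136 with an estimated correlation), among them Ccl4, from 1637 ± 274 to 4423 ± 1488 CPM. Of 16 heat shock genes 7 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 0.331 with an estimated correlation), among them Hspa1b, from 841 ± 390 to 2573 ± 1107 CPM. fry, which tests each list on its own, called 11 lists, 9 of them among the 14 that camera called.

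In these cells 1391 of 11671 genes passed the threshold, 776 higher and 615 lower. The count was 621 without PBS replicate 1, 741 without UV-TMPs replicate 2 and 256 without UV-TMPs replicate 1. The largest folds downward, Lcn2 and the acute-phase gene Saa3 (chromosome 7, 46361422 to 46365576), were highest in PBS replicate 3. Saa3 was at 4012 ± 6487 CPM in PBS and 61.4 ± 27.6 CPM in UV-TMPs, with a log2 change of −6.02 ± 1.37 that was −2.114, and still called, without PBS replicate 3. Without UV-TMPs replicate 1, the calls of Gbp4 (2.50 ± 0.54, then 2.16), Fkbp5 (−2.14 ± 0.49, then −2.05), Hspa1b (1.62 ± 0.34, then 1.20), Saa3 (−5.84) and Lcn2 (−6.05) ended. The call of Fkbp5 also ended without PBS replicate 1 (−2.12) or UV-TMPs replicate 2 (−2.13), that of Saa3 without UV-TMPs replicate 2 (−5.85), and that of Lcn2 without PBS replicate 3 (−2.00), UV-TMPs replicate 2 (−5.95), UV-TMPs replicate 3 (−6.53) or MW-TMPs replicate 1 (−6.14).

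**Figure D2:**
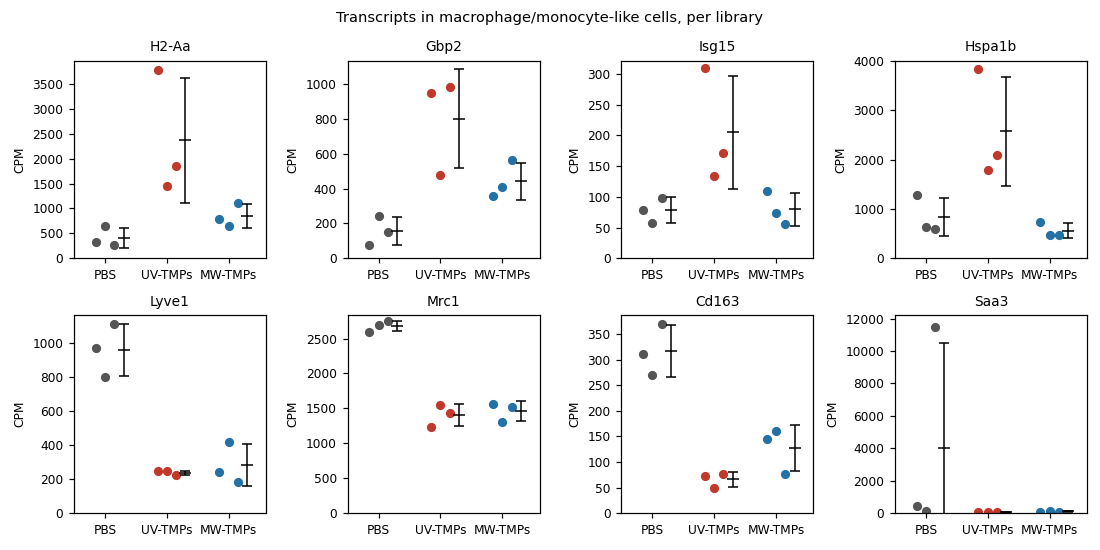
Level in macrophage/monocyte-like cells (CPM, linear axis) of 8 genes in the PBS, UV-TMPs and MW-TMPs groups, with a point per library and the mean and SD of 3 libraries. H2-Aa had a mean of 407 CPM in PBS and 2367 CPM in UV-TMPs, and Lyve1 one of 960 CPM in PBS and 281 CPM in MW-TMPs.

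In dendritic cell-like cells, with 3 UV-TMPs and 2 PBS libraries, interferon-stimulated genes were higher after UV-TMPs. The antiviral gene Ifit1 (chromosome 19, 34618271 to 34632174) rose from 49.5 ± 26.4 (n = 2) to 752 ± 62.0 CPM (n = 3), a log2 change of 3.91 ± 0.33. Cxcl9 rose by 3.30 ± 0.38 to 1116 ± 389 CPM, and Ccl4 from 830 ± 206 to 4073 ± 112 CPM. The type I interferon gene Ifna2 had 74 counts in UV-TMPs and 0 in PBS, at least 11.6-fold higher, and shares 21.2% of its end with other genes. Cmpk2 was at least 6.73-fold and Calhm6 at least 6.11-fold higher. The ratio was 24.0 for the cytokine Lif (95% interval 6.47 to 200.5), 24.9 for Tgtp1 (4.28 to 1002), which shares 100% of its end with other genes, and 23 for the itaconate-producing enzyme Acod1 (3.94 to 928). Xcr1, a chemokine receptor of the dendritic cells that present antigen to CD8 T cells, fell from 170 ± 5.66 to 40.8 ± 22.8 CPM, Cadm1 fell by 2.02 ± 0.47, and the chemokine Ccl17 fell from 640 ± 58.7 to 202 ± 103 CPM. Xcr1 and Cadm1 are among the markers that gave this class its name. At Leiden resolution 2, dendritic cell-like cells lay in a cluster of 268 cells with Cd209a and one of 74 with Ccr7 and Ccl22. PBS held 70 cells of the class, at most 36 in a library. A shift between kinds of dendritic cell is not parted from a change inside them here.

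Of 22 type I interferon genes 15 rose and 0 fell in dendritic cell-like cells (21 and 0 adjusted over the list alone, adjusted p = 2.14e-42, and 0.0243 with an estimated correlation). Of 20 interferon gamma genes 10 rose (16 adjusted over the list alone), of 18 class I genes 5 rose (15 adjusted over the list alone), and of 16 chemokine genes 5 rose and 1 fell (6 and 1 adjusted over the list alone). These 3 lists had an adjusted p of 0.0408 with an estimated correlation. Of 6 cytotoxic effector genes 3 rose (5 adjusted over the list alone), with an adjusted p of 0.0437 with an estimated correlation. The other 10 lists past the threshold had adjusted p-values between 0.187 and 0.481 with it. In all, 99 of 5653 genes passed the threshold, 84 higher and 15 lower. In the 4 fits without a library that could be run, the calls of 5 of the 12 genes named by fold (Ifna2, Lif, Xcr1, Ccl17 and Gpr141b) held throughout. These left out UV-TMPs replicate 1, 2 or 3 or MW-TMPs replicate 3. A PBS library could not be left out, since only 2 entered, so the calls were not checked for either of them.

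In malignant-like cells, the interferon gamma list also lay higher after UV-TMPs at the preset correlation (adjusted p = 0.926 with an estimated correlation). A malignant-like cluster led by Gbp2 and Igtp held 0.707% ± 0.397 of kept cells in PBS and 6.10% ± 5.24 in UV-TMPs, and a shift between clusters is not parted from a change inside them here. Gbp2 rose from 19.4 ± 8.45 to 101 ± 71.9 CPM (log2 change 2.38 ± 0.48), Igtp by 2.09 ± 0.40 and Ctla4, a brake on T cells, from 45.0 ± 9.24 to 179 ± 86.6 CPM. Atp10d rose from 11 ± 2.04 to 34.9 ± 3.82 CPM. The glycolytic enzyme Eno1 fell from 389 ± 91.4 to 118 ± 31.8 CPM while Eno1b, which shares 93.4% of its end with another gene, rose from 55.7 ± 4.54 to 181 ± 116 CPM. Hmga1, a chromatin protein that shares 87.0%, fell from 290 ± 96.7 to 88.0 ± 21.7 CPM, and Fxr2, Psmd3 and Dnase2a fell by 1.36 to 1.47.

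Of 23 interferon gamma genes 13 rose and 1 fell in malignant-like cells (14 and 1 adjusted over the list alone, adjusted p = 1.31e-05), and of 18 class I genes 10 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 0.000685). H2-K1 rose from 709 ± 87.5 to 1367 ± 417 CPM. Hypoxia and glycolysis genes (9 of 28 rose and 1 fell) and heat shock genes (3 of 16 rose and 0 fell), the same numbers adjusted over the list alone, had adjusted p-values of 0.0405 and 0.0454. All 4 lists had an adjusted p of 0.926 with an estimated correlation. The hypoxia call ended in 5 of the 9 fits without a library (highest adjusted p 0.256, without PBS replicate 3) and the heat shock call in 6 (0.425, without PBS replicate 3).

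In malignant-like cells 5284 of 19606 genes passed the threshold, 2594 higher and 2690 lower. The count was 3268 without PBS replicate 1, 3257 without PBS replicate 3, 2957 without UV-TMPs replicate 1 and 3275 without UV-TMPs replicate 2. Without UV-TMPs replicate 1 the call of Gbp7 (1.57 ± 0.38) ended, at 1.08, and without PBS replicate 3 that of Lcn2 (−4.79 ± 1.16), at −1.51. Of the called genes, 3416 were also tested in macrophage/monocyte-like cells, and 90.9% had the same sign there. Over all 11383 genes tested in both it was 75.1%. Both classes come from the same libraries: in the 9 other splits of the 6 libraries, 72.8% to 88.4% of as many top genes had the same sign, and 64.2% to 72.2% of all genes. Each of those splits holds unequal numbers of both groups on each side, so part of the group difference stays in it. The splits are thus no baseline for agreement from shared libraries alone. The log2 changes of the 3416 called genes in the 2 classes had a Pearson r of 0.773 across genes, which are not independent replicates.

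**Figure D3:**
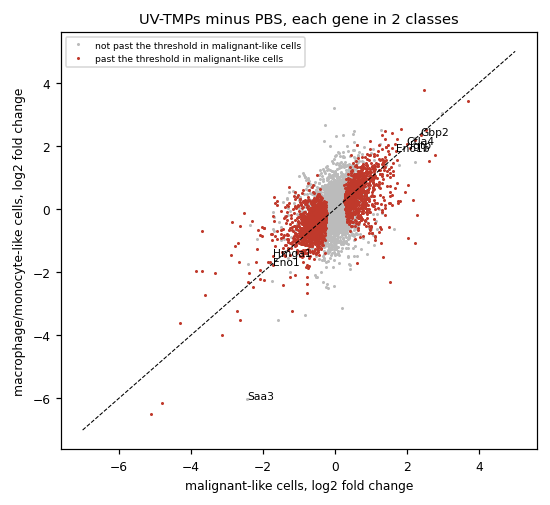
Log2 change of UV-TMPs against PBS in malignant-like cells (x axis) and in macrophage/monocyte-like cells (y axis), 1 point per gene for 11383 genes tested in both. The 3416 genes past the threshold in malignant-like cells are coloured, and 90.9% of them have the same sign on both axes. The dashed line marks equal changes.

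MW-TMPs against PBS asks what the microwave-made particles did to the tumour. The resident macrophage marker Lyve1 was lower after MW-TMPs, from 53.5 ± 17.1 to 8.55 ± 1.95 CPM in the whole tumour (log2 change −2.64 ± 0.23, adjusted p = 0.00574). Within macrophage/monocyte-like cells it fell from 960 ± 155 to 281 ± 124 CPM (log2 change −1.78 ± 0.25, adjusted p = 0.0431). There Mrc1, itself a marker used to name the class, fell from 2680 ± 75.5 to 1460 ± 140 CPM, and Deptor, an inhibitor of mTOR, by 1.09 ± 0.17. The cluster led by Lyve1, with Mrc1 and Cd163, held 44.6% ± 3.20 of the class in PBS and 18.9% ± 6.37 in MW-TMPs, so a shift between clusters is not parted from a change inside them here either. The vasoactive peptide gene Adm, induced by hypoxia (chromosome 7, 110226858 to 110229027), rose from 9.01 ± 1.99 to 29.4 ± 5.63 CPM. The nucleic acid sensor Zbp1 rose from 39.1 ± 2.51 to 77.6 ± 1.10 CPM, Basp1 by 1.10 ± 0.16, and Tmsb10, which shares 44.9% of its end with other genes, by 1.25 ± 0.19.

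Genes of hypoxia and glycolysis lay higher after MW-TMPs as a list. In the whole tumour 0 of 28 passed over all genes and 20 rose and 0 fell adjusted over the list alone (adjusted p = 1.73e-23, and 0.220 with an estimated correlation). Vegfa (chromosome 17, 46327919 to 46343309) was at 65.5 ± 2.90 CPM in PBS and 109 ± 5.51 CPM in MW-TMPs (log2 change 0.74 ± 0.10, adjusted p = 0.125). The carbonic anhydrase Car9 was at 3.44 ± 1.05 and 11 ± 5.04 CPM, and the glucose transporter Slc2a1 at 137 ± 21.0 and 249 ± 56.4 CPM. The coagulation factor F3 had a log2 change of 0.87 ± 0.13 (adjusted p = 0.125). In malignant-like cells 0 of the 28 passed over all genes and 21 rose and 1 fell adjusted over the list alone (adjusted p = 3.04e-26, and 0.215 with an estimated correlation). With this list moved the share of kept cells of a malignant-like cluster led by Adm, Ndrg1 and Slc2a1, 3.39% ± 2.56 in PBS and 10.3% ± 4.56 in MW-TMPs, and that of another led by Adm, 2.84% ± 1.94 and 8.65% ± 0.953. In macrophage/monocyte-like cells 1 rose over all genes and 14 rose adjusted over the list alone (adjusted p = 1.77e-14, and 0.224 with an estimated correlation).

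The interferon gamma list was also higher. In malignant-like cells 0 of its 23 genes passed over all genes and 13 rose adjusted over the list alone (adjusted p = 9.53e-17, and 0.351 with an estimated correlation), and in macrophage/monocyte-like cells 0 of 22 passed and 14 rose adjusted over the list alone (adjusted p = 1.15e-20, and 0.178 with an estimated correlation). Clusters moved with this list: the malignant-like one led by Gbp2 and Igtp held 0.707% of kept cells in PBS and 3.15% ± 1.09 in MW-TMPs, and the macrophage one led by Cxcl9, with Cd74 and H2-Aa, 8.34% and 27.1% ± 5.24 of its class. In macrophage/monocyte-like cells Irf1 was at 99.7 ± 24.5 CPM in PBS and 217 ± 30.7 CPM in MW-TMPs. Of 18 class I genes in these macrophages, 0 passed over all genes and 12 rose adjusted over the list alone (adjusted p = 9.32e-13, and 0.224 with an estimated correlation). Genes of alternatively activated macrophages were lower as a list in the whole tumour, where 1 of 20, Lyve1, fell over all genes, and 10 fell and 1 rose adjusted over the list alone (adjusted p = 1.13e-07, and 0.264 with an estimated correlation). Of 23 phagocytosis and efferocytosis genes 0 passed over all genes and 12 fell adjusted over the list alone (adjusted p = 3.46e-06, and 0.375 with an estimated correlation). The macrophage/monocyte-like share, 8.50% in PBS and 4.79% in MW-TMPs, moved with these lists.

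Few single genes passed the threshold for MW-TMPs against PBS with edgeR: 1 of 21088 in the whole tumour, 0 of 19606 in malignant-like cells and 9 of 11671 in macrophage/monocyte-like cells. At an unadjusted p under 0.05 there were 3315, 2604 and 1583 genes, against up to 2083, 2293 and 973 in the 9 other splits of the 6 libraries, and DESeq2 called 527, 220 and 226. With 1 library left out, edgeR called 0 to 84 genes in the whole tumour and 0 to 175 in malignant-like cells. In malignant-like cells the smallest adjusted p, 0.0623, was that of Vegfa (0.73 ± 0.10), Atp10d (1.10 ± 0.17) and Lyve1. There Lyve1 lay at only 0.523 CPM in PBS and 0.0971 CPM in MW-TMPs, against 960 and 281 CPM in macrophage/monocyte-like cells. A change of Lyve1 in the malignant-like cells themselves is therefore not shown. The call of Lyve1 in the whole tumour ended without MW-TMPs replicate 2 (log2 change −2.68) or 3 (−2.48). Of the 6 macrophage genes named by fold, 0 kept their call in all 9 fits without a library, and the count there went from 0 without PBS replicate 1 or MW-TMPs replicate 3 to 135 without PBS replicate 2. The log2 change went with transcript length here too (Spearman −0.183 in the whole tumour and −0.235 in macrophage/monocyte-like cells), and with that trend taken out 1 of the 9 macrophage genes was still called, while the median size of their log2 changes went from 1.10 to 1.00.

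MW-TMPs against UV-TMPs asks how the 2 kinds of particle differ. Antibody transcripts were lower after MW-TMPs: Igkc was at 12.2 ± 2.07 CPM in UV-TMPs and 0.113 ± 0.0744 CPM in MW-TMPs (adjusted p = 0.0035), and Jchain fell by 5.63 ± 0.39. Both rest mostly on the 3 cells named above, and the T cell-like class of MW-TMPs held 0 such cells. So few cells do not establish a difference between the groups. The inducible chaperones Hspa1a and Hspa1b were lower in macrophage/monocyte-like cells, from 2633 ± 877 to 765 ± 133 CPM and from 2573 ± 1107 to 559 ± 149 CPM. Slc13a3, a dicarboxylate transporter, rose there from 14.3 ± 0.95 to 35.3 ± 2.07 CPM, and Tmem120a rose by 1.46 ± 0.19, while Fam43a and the signalling enzyme Plcg2 fell by 1.28 and 0.69. In malignant-like cells the stress-induced gene Ndrg1 rose from 67.3 ± 21.8 to 135 ± 25.8 CPM (the cluster led by Adm, Ndrg1 and Slc2a1 held 4.30% ± 2.50 of kept cells in UV-TMPs and 10.3% ± 4.56 in MW-TMPs), and Tmem120a (1.06), Fxr2 (1.01) and Hmga1 (1.47) rose, while Xkr6 (−1.38), Palb2 (−1.04), Dgka (−0.81) and Nlrp4e (−1.18) fell. In the whole tumour Hoxd9 (0.86), Tjp1 (0.54) and Ahcyl1 (0.50) rose, Usf1 and Gstp1, which share 35.7% and 61.1% of their ends with other genes, rose by 0.72 and 1.19, and Atp6v0a4 (−1.40) and Ryr2 (−1.34) fell.

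By list, 0 of 13 class II genes passed over all genes in the whole tumour and 9 fell adjusted over the list alone (adjusted p = 1.14e-05, and 0.449 with an estimated correlation). The dendritic cell-like share, 0.683% in UV-TMPs and 0.243% in MW-TMPs, moved with this list. In macrophage/monocyte-like cells 0 of 11 passed and 8 fell adjusted over the list alone (adjusted p = 1.64e-06, and 0.322 with an estimated correlation). H2-Aa was there at 2367 ± 1248 CPM in UV-TMPs and 851 ± 243 CPM in MW-TMPs, and the cluster led by Cxcl9 held 39.4% ± 24.2 and 27.1% ± 5.24 of the class. Of 16 heat shock genes in these cells 2 fell over all genes and 8 adjusted over the list alone (adjusted p = 4.26e-09, and 0.322 with an estimated correlation), and of 25 type I interferon genes 0 passed over all genes and 11 fell and 1 rose adjusted over the list alone (adjusted p = 5.13e-08, and 0.392 with an estimated correlation). Of 21 cytotoxic effector genes in the whole tumour 0 passed over all genes and 4 fell adjusted over the list alone (adjusted p = 8.12e-06, and 0.486 with an estimated correlation). The T cell-like share, 0.705% in UV-TMPs and 0.355% in MW-TMPs, and the NK cell-like share, 0.407% and 0.190%, moved with it.

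In all, 77 genes passed the threshold in the whole tumour (10 higher and 67 lower after MW-TMPs), 436 in malignant-like cells (123 and 313) and 14 in macrophage/monocyte-like cells (4 and 10). The log2 change in the whole tumour went with transcript length (Spearman 0.264). This balance depended on the setting: in the whole tumour 873 were higher and 873 lower with DESeq2, 179 and 174 with no low-count filter, and 345 and 141 without UV-TMPs replicate 3. In malignant-like cells 830 were higher and 889 lower with DESeq2, and 521 and 303 without UV-TMPs replicate 3. The whole-tumour count was 2 without UV-TMPs replicate 1, MW-TMPs replicate 1 or MW-TMPs replicate 2 and 486 without UV-TMPs replicate 3. Of 16 named genes, 2 kept their call in all fits, Igkc and Jchain, which rest mostly on 3 cells. The malignant-like count went from 0 without MW-TMPs replicate 2 to 824 without UV-TMPs replicate 3, and 0 of the 12 malignant-like genes and 0 of the 6 macrophage genes named by fold kept their call in all 9 fits. The macrophage count was 0 without UV-TMPs replicate 1 or 3 or any one of the MW-TMPs libraries, and when host cells with more than 3 LLC marker UMIs were left out.

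Hmgb1 (chromosome 5, 148983445 to 149121815), the gene of the series title, did not pass the threshold in any of the 11 edgeR fits. In the whole tumour its level was 632 ± 93.0 CPM in PBS, 541 ± 46.6 CPM in UV-TMPs and 711 ± 13.7 CPM in MW-TMPs. In malignant-like cells it was 698 ± 104, 583 ± 54.9 and 748 ± 14.3 CPM, and in macrophage/monocyte-like cells 249 ± 26.1, 205 ± 10.8 and 261 ± 8.96 CPM. DESeq2 called it higher in MW-TMPs than in UV-TMPs in the whole tumour (log2 change 0.4216) and in malignant-like cells (0.3836). A transcript level says nothing about where the protein is. Calr, whose protein on dying cells is an uptake signal, was at 936 ± 142, 991 ± 22.5 and 969 ± 79.6 CPM in the whole tumour and was not called. Tlr4, a receptor of HMGB1, fell after UV-TMPs from 24.9 ± 4.20 to 15.9 ± 3.99 CPM in the whole tumour (log2 change −0.65 ± 0.18, adjusted p = 0.027), a call that ended without PBS replicate 1 (−0.55), PBS replicate 3 (−0.61), UV-TMPs replicate 1 (−0.60) or UV-TMPs replicate 2 (−0.54). In MW-TMPs it lay at 17.6 ± 1.76 CPM and was not called. The list of HMGB1 and ATP receptors and their adaptors lay lower in MW-TMPs than in PBS in the whole tumour (adjusted p = 0.00763, and 0.547 with an estimated correlation), a call that ended without PBS replicate 3 (0.0949) or MW-TMPs replicate 2 (0.0507). It was not called within malignant-like or macrophage/monocyte-like cells. The macrophage/monocyte-like share, 8.50% in PBS and 4.79% in MW-TMPs, moved with it, and within that class Tlr4 was at 85.3 ± 6.39 and 83.8 ± 2.91 CPM. Ager, another receptor of HMGB1, lay at 0.318 ± 0.0886 CPM in PBS, 0.363 ± 0.0525 CPM in UV-TMPs and 0.344 ± 0.0119 CPM in MW-TMPs.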

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

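The fit that compares macrophage/monocyte-like with malignant-like cells, the rule that names its genes, and the tests of a shift common to all cells, of transcript length, of PBS replicate 3, of a swap and of the other splits were chosen after the results were seen.

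The change after treatment was tested for a difference between macrophage/monocyte-like and malignant-like cells of the same libraries, as an interaction in one edgeR fit. It passed the threshold for 37 genes for MW-TMPs against PBS (25 more positive in macrophages and 12 more negative), 273 for UV-TMPs against PBS (142 and 131) and 36 for MW-TMPs against UV-TMPs (14 and 22). On simulated counts, the test found 28.5% of 200 genes changed by a fold of 2 in macrophages alone, and called 0 of 200 changed in both classes. Part of the genes named below lie higher in malignant-like cells than in macrophages. Whether RNA from malignant cells in the macrophage sums adds to their differences was not tested. The genes below hold at least 10 CPM in both classes and have the largest differences, given as the log2 change in macrophages minus that in malignant-like cells. For MW-TMPs against PBS they were the endothelial protein C receptor Procr (1.8528, adjusted p = 0.011), the antioxidant enzyme Srxn1 (1.4727, adjusted p = 0.011) and Selenom (1.4279, adjusted p = 0.0281), and downward Clcn5 (−0.8056, adjusted p = 0.0143), Gja1 (−0.7678, adjusted p = 0.0207) and Mon2 (−0.7652, adjusted p = 0.0494). For UV-TMPs against PBS they were the class II chaperone H2-DMb1 (1.5452, adjusted p = 0.00777), Socs1 (1.4588, adjusted p = 0.00173) and Cnn3 (1.4270, adjusted p = 0.00567), and downward Saa3 (−2.8637, adjusted p = 0.00285), Ap5s1 (−1.3590, adjusted p = 0.00173) and Kank2 (−1.1937, adjusted p = 0.0405). The macrophage change of Saa3 alone went from −6.02 to −2.114 without PBS replicate 3, so its difference leans on that library. For MW-TMPs against UV-TMPs they were the stress cytokine Gdf15 (2.1230, adjusted p = 0.0238), Gpnmb (1.4474, adjusted p = 0.0238) and the glutathione synthesis gene Gclm (1.0341, adjusted p = 0.0238), and downward Tnfaip6 (−1.8994, adjusted p = 0.0383), Pramel12 (−1.4229, adjusted p = 0.0254) and Hspa1b (−1.3755, adjusted p = 0.0238).

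A first pattern is the large number of genes past the threshold for UV-TMPs against PBS in malignant-like cells. Transcript length as the whole cause is argued against, since 4599 genes passed after each library's length trend was taken out, against 5087 of the same genes with a known length before. Of those 5087, 3854 kept their call and direction. Reads shared between near-identical genes are argued against too: 10.36% of the called genes share over 10% of their end with another gene, against 9.67% of the others. A shift common to all cells of a library cannot be told apart from other causes. Of the 1285 called genes that macrophages hold at least as high, 86.23% had the same sign in macrophages. The same share of top genes in the 9 other splits of these libraries ran from 70.2% to 86.1%. Those splits still hold part of the group difference, so they are no baseline for shared libraries alone. The test therefore cannot decide whether there was such a shift. Such a shift may be technical, as in library preparation, or a response of every cell to the treatment, and the labels give no batch that would part them.

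A second pattern is the rise of interferon and MHC genes in macrophage/monocyte-like cells after UV-TMPs. RNA from malignant cells is argued against as the cause for most members, since the median gain in macrophages was 4.294 times the whole level of malignant-like cells, and above 1 for 30 of the 37 called members tested. For the other 7 it stays open, and H2-DMb2 was not tested. A single library is argued against, since the highest adjusted p of the interferon gamma list over the 9 fits without a library was 2.64e-19 at the preset correlation, though with an estimated one the list was not called in the full fit either (0.161). A shift common to all cells cannot be told apart from a macrophage response for the class II list: its difference between macrophages and malignant-like cells had an adjusted p of 8.13e-08 at the preset correlation and 0.0836 with an estimated one, and the correlation between genes keeps it open.

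Another pattern is the high level of Saa3, Lcn2 and Csf3 in PBS. In macrophage/monocyte-like cells PBS replicate 3 held 11500 CPM of Saa3, 1100 CPM of Lcn2 and 64.3 CPM of Csf3, and the others held 427 and 108, 40.7 and 1.29, and 0.985 and 0 CPM, so that for Lcn2 and Csf3 one PBS library lay below every UV-TMPs library (3.5 to 7.46 CPM of Lcn2 and 0.173 to 0.269 CPM of Csf3). Without PBS replicate 3 the call of Lcn2 ended (−2.00, adjusted p = 0.138), while Saa3 was still past the threshold at −2.114, less than 0.5 of −6.02. For Saa3 that library alone and a difference of the group therefore cannot be told apart. For Lcn2 and Csf3 no difference beyond that library was shown in these cells. In malignant-like cells the lowest PBS library lay above the highest UV-TMPs library for Csf3 (1.17 against 0.734 CPM). For Lcn2 it did not (2.87 against 3.93 CPM). A swap of PBS replicate 3 with a UV-TMPs library is argued against, since along the genes called without it, it lay at 0.047 of the way from PBS (0) to UV-TMPs (1). A tumour with more inflammation may explain that library, but the data used here hold no measurement of it besides the RNA of that library. In that RNA, 45 of the 49 neutrophil-like cells of PBS were found. It also gave 79.8% of the cells of the malignant-like cluster led by Csf3, Lcn2 and Nos2.

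Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In the whole tumour the real split gave 1 gene for MW-TMPs against PBS, 5016 for UV-TMPs against PBS and 77 for MW-TMPs against UV-TMPs, and the highest other split gave 0 each time, so that 1 of 10 splits gave as many. In malignant-like cells the real splits gave 5284 and 436 for the last 2 of these and the highest other 0 (1 of 10 splits each), while for MW-TMPs against PBS 10 of 10 splits gave 0. In macrophage/monocyte-like cells the real splits gave 9, 1391 and 14 and the highest others 1, 1 and 0, and in T cell-like cells 28 and 1, so that 1 of 10 splits gave as many each time.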

How the results depend on the processing

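Leaving out the cells with the highest doublet scores, the common relative UMI minimum and leaving out mixed host cells were chosen after the data were seen. The causes of the differences below were not tested. Only the counts for UV-TMPs against PBS in the whole tumour and in malignant-like cells stayed within 1.5 times their value under every alternative except some left-out libraries. In order, MW-TMPs against PBS, UV-TMPs against PBS and MW-TMPs against UV-TMPs, the counts with 1 library left out ranged from 0 to 84, 2417 to 5005 and 2 to 486 genes in the whole tumour, 0 to 175, 2957 to 5529 and 0 to 824 in malignant-like cells, and 0 to 135, 256 to 1348 and 0 to 63 in macrophage/monocyte-like cells. They ranged from 71 to 118 in dendritic cell-like cells (4 fits could be run) and 3 to 55 in T cell-like cells (7 fits). The counts of genes that differ between macrophages and malignant-like cells ranged from 21 to 312, 98 to 632 and 5 to 165.

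For MW-TMPs against PBS, DESeq2 called 527 genes in the whole tumour, 220 in malignant-like and 226 in macrophage/monocyte-like cells. No low-count filter gave 15, 76 and 648, and the replicate block 79, 6 and 24. Only the 2 groups gave 0 in the whole tumour and 2 in macrophages, and the length correction 1 in macrophages (for MW-TMPs against UV-TMPs there 8, against 2 before it among the genes with a known length). RLE scaling gave 6 and Leiden resolution 2 gave 10 in malignant-like cells. For MW-TMPs against UV-TMPs, DESeq2 called 1746, 1719 and 184, no filter 353, 1037 and 567, and only the 2 groups 2, 179 and 75. The replicate block gave 158 in the whole tumour and 57 in macrophages, and RLE 170 in the whole tumour. The stricter cell filter gave 2 in macrophages, leaving out the highest doublet scores 2, and leaving out mixed host cells 0. For UV-TMPs against PBS, no filter gave 2167 genes in macrophages and 232 in dendritic cell-like cells, and the block 55 in the latter. In T cell-like cells DESeq2 gave 45, no filter 216, the block 50, the stricter filter 6, the doublet scores 43 and the common UMI minimum 48. Thbs1, called higher there in MW-TMPs than in UV-TMPs, reversed to −1.8193 under that minimum. The type I interferon list in the whole tumour, lower in MW-TMPs than in UV-TMPs, pointed upward, not past the threshold, without UV-TMPs replicate 1, with adjusted p-values from 1.6369e-06 to 0.683 over the left-out libraries. RLE moved the share of higher genes for MW-TMPs against UV-TMPs from 13% to 33.5% in the whole tumour.

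With an estimated correlation, 0 lists passed in every class and comparison except 5 in dendritic cell-like cells, against 4 to 15 at the preset one. fry passed 0 lists in malignant-like and T cell-like cells, and in the whole tumour 0, 0 and 1, in macrophages 0, 11 and 2 and in dendritic cell-like cells 5. The replicate block gave 8 lists in malignant-like cells for MW-TMPs against UV-TMPs. With 1 library left out, list counts ranged from 9 to 13, 6 to 12 and 10 to 17 in the whole tumour, 9 to 12, 2 to 6 and 1 to 9 in malignant-like cells, and 11 to 16, 12 to 17 and 9 to 13 in macrophages, 14 to 15 in dendritic and 8 to 14 in T cell-like cells.

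Class shares passed the threshold in 6 alternative fits. With immune cells as denominator these were T cell-like for MW-TMPs (1.3032) and UV-TMPs (1.4524) against PBS, with mixed host cells left out T cell-like for UV-TMPs against PBS (2.4274), with 1 library left out T cell-like for UV-TMPs against PBS (1.217 to 2.0573, past the threshold without PBS replicate 1), and with the replicate block endothelial-like (−0.9865) and macrophage/monocyte-like (−0.8584) for MW-TMPs against PBS. Hmgb1 for MW-TMPs against UV-TMPs passed with DESeq2 in the whole tumour (0.4216) and in malignant-like cells (0.3836). The replicate number was not taken to pair the libraries, since the rule used needs a residual correlation over 0.1 in every pair of equal numbers. Those pairs ran from −0.145 to 0.213 in the whole tumour and −0.0979 to 0.184 in macrophages. In macrophages 4 of 9 were over 0.1, all 3 of replicate 3 among them, and pairs of unequal numbers ran from −0.184 to 0.163. A pairing of only some libraries could not meet this rule, so the rule cannot exclude one. In macrophages 5 of 9 libraries were closest to one of their own number, and 4 of 9 in the whole tumour. Depth limits dendritic and T cell-like cells, whose deepest libraries held 0.516 and 0.72 times 1e6 UMIs, and neutrophil-like and NK cell-like cells could not be tested. Too few dendritic cell-like cells were left for a fit under the common UMI minimum, and too few dendritic and T cell-like cells without mixed host cells.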

Other observations

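The lists and the rule that names their members were fixed before the data were examined, the members named were picked by that rule from the results, and the unnamed clusters were looked at only afterwards.

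The list of ferroptosis and oxidative stress genes lay higher in macrophage/monocyte-like cells after MW-TMPs. Against UV-TMPs, 0 of 18 passed over all genes and 9 rose adjusted over the list alone (adjusted p = 4.11e-08, and 0.15 with an estimated correlation). Against PBS, 0 passed over all genes and 7 rose adjusted over the list alone (adjusted p = 2.38e-06, and 0.154 with an estimated correlation). Srxn1 was at 15.2 ± 4.83 CPM in PBS, 18.8 ± 3.14 CPM in UV-TMPs and 36.8 ± 5.58 CPM in MW-TMPs. The glutathione synthesis gene Gclm was at 42.7 ± 9.46 CPM in UV-TMPs and 98.1 ± 29.5 CPM in MW-TMPs. Ftl1, a ferritin chain that shares 67.6% of its end with other genes, was at 3667 ± 783 and 7443 ± 1958 CPM.

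In T cell-like cells, MW-TMPs against UV-TMPs, 28 of 8422 genes passed the threshold, 5 higher and 23 lower. Granzyme B (Gzmb) fell from 2467 ± 296 to 1250 ± 178 CPM and the chemokine Ccl4 from 805 ± 461 to 210 ± 15 CPM. Of 21 cytotoxic effector genes 3 fell over all genes and 7 adjusted over the list alone (adjusted p = 1.38e-08, and 0.397 with an estimated correlation). In this class 42.3% of cells held more than 3 UMIs of LLC markers, and without them too few cells were left for a fit. A fall of Gzmb or of this list is therefore not parted from a change in the part of malignant RNA in the sums. Antibody genes in this class were lower: Igha was at least 194-fold and Jchain at least 61.7-fold lower, with 0 counts in MW-TMPs, and C1qa, a macrophage gene, was at least 10.6-fold lower. In UV-TMPs 3 of the 219 cells of the class, 1 in each library, held all 750 Igha and all 238 Jchain UMIs of the class. Cxcl1 rose from 284 ± 49.1 to 665 ± 129 CPM and Hmga1, a gene of the malignant-like cells, from 38.8 ± 5.90 to 161 ± 78.5 CPM. Igkc and Jchain were the only 2 of 11 genes named by fold that kept their call in the 7 fits without a library that could be run. The count was 3 without UV-TMPs replicate 1 or MW-TMPs replicate 2.

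Of the unnamed clusters, the most abundant, with Lum and Dpt among its leading genes, held 10.4% ± 3.69 of cells in PBS, 4.52% ± 3.29 in UV-TMPs and 5.06% ± 1.87 in MW-TMPs (SD, n = 3). This cluster had 859 CPM of the LLC gene Hmga2 and 2.0 CPM of Xist. A cluster of 904 cells with monocyte-like genes held 1.09%, 1.05% and 0.886%. It had 624 CPM of the LLC gene Hmga2, 57.3 CPM of Xist and a median doublet score of 0.284, the highest of all clusters. One of 577 cells led by S100a8 and S100a9, with 798 CPM of Hmga2, held 0.997% ± 0.914, 0.344% and 0.675%. One of 92 cells led by the osteoclast genes Ctsk, Acp5 and Mmp9 held 0.0679%, 0.196% and 0.0562%. Among the malignant-like clusters, one led by Csf3, Lcn2 and Nos2 had 79.8% of its cells from PBS replicate 3.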
